A study of Mus musculus with 24 samples.

How the data were processed

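Striatum was micropunched from 12 female C57BL/6 mice, 3 in each combination of Cntnap2 genotype and prenatal condition, and DNA and RNA came from the same tissue, per the labels. Ear-tagging at postnatal day 12 and weaning at day 18 were the same for all. RNA libraries were made with a NuGen kit and random primers, per the labels, and reads were assigned with RSEM and Bowtie against mm9 (NCBIM37), per the submitters' processing notes. The versions of these tools for RNA are not given in the sources used here. For each gene and transcript the deposited files give the expected count, the TPM and the FPKM that RSEM computed, with 1 file per library and no pooling, per the file headers. DNA enriched for 5hmC was sequenced, and its reads were aligned with Bowtie 0.12.7 to mm9, per the submitters' processing notes. The deposited 5hmC tables hold whole-number read counts per region and library for 5 comparisons, per the file headers. How the regions were chosen is not given in the sources used here. The regions were 1001 to 17700 bp long, and 1 region on chromosome 2 held 11.8 to 18.8% of the counts of a table.

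The labels use the replicate numbers to name a mouse within its group and do not say that a number marks a shared litter, batch or day. Replicates are separate mice, though mice of 1 litter may share a group, so p-values measure the spread between these mice. Replicate libraries of a group differed by more than sampling noise (chi-square per gene 9.22 to 223; per 5hmC region 1.07 to 2.41), so none was counted as a duplicate. The 5hmC tables were tested one at a time because each has its own set of regions.

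Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr, scaled by TMM and fitted with edgeR 4.0.16 (glmQLFit with robust dispersion and glmQLFTest) in R 4.3.3, over all 12 libraries with the 4 group means. The 8 contrasts were 5 pairwise differences, the interaction, and the stress and genotype differences averaged over the other factor. P-values were adjusted by Benjamini-Hochberg within a contrast and called at 0.05, two-sided. The biological coefficient of variation was 0.256. Of the 15955 genes tested, 664 have no symbol and are given by their identifier. Cntnap2 was also compared as log2(TPM + 1) by a two-sided exact permutation test of 6 against 6 mice, which can reach p = 0.00216; 3 against 3 cannot go below 0.1. Intervals are 95% and, like the floor of 3 counts over a group, cover counting error only.

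The 34 gene lists were fixed before the data were examined, as were the contrasts, the main tests, the rule for named genes and most alternatives. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with prior count 2 and a correlation between genes preset to 0.01, adjusted over lists within a contrast. The estimated correlation had a median of 0.310 over the lists, far above the preset, so camera was also run with it. Only the immature neuron list held then, in stressed mice by genotype and in the genotype average. No list was called by fry. Fits that left out a library used the preset correlation only. A list member was also adjusted over the list alone. All lists called are described for the genotype contrasts in controls, in stressed mice and averaged. For the other contrasts, the lists described were chosen after their values were seen. Among those called and not described are the autism risk, glutamate receptor, heat shock and oxidative phosphorylation lists.

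The planned description of the 5hmC tables assumed that they held no sample values. As they hold counts, each table was tested with edgeR's quasi-likelihood test (TMM, robust, called at an adjusted p of 0.05), a choice made after seeing the files. Regions were compared between tables with bedtools 2.31.1 at a minimum overlap of 1 bp, and their positions are those of the files, in mm9. Chromosomes of genes were looked up by symbol in a RefSeq table of GRCm38.p6, which gave a chromosome for 15017 genes tested, 94.1%; none of its coordinates was used. Links between 5hmC regions and RNA need a gene annotation of mm9 and were not analysed here.

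Named genes are Cntnap2, all called genes and, in contrasts with fewer than 5 calls, the 5 with the smallest p in each direction; for lists, the 2 members with the smallest p; for 5hmC, the 3 regions with the smallest p in each direction of a table and all called ones. Gm6736 is named as a pseudogene, and the lookup by symbol gave no chromosome for Gm10800. Reads of both could come from near-identical copies, so their origin is uncertain. Antisense and overlapping genes cannot be told apart, since strand use is not stated.

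On simulated data for the control genotype comparison, 18.5% of 200 genes changed 2-fold were recovered with 0 false calls among 15838 genes, and 87.5% of those changed 4-fold with 6 false calls among 15823. With 200 of 38107 5hmC regions changed, 30% were recovered at 1.5-fold (7 false calls) and 91% at 2-fold (10 false calls). A list of 20 genes shifted in simulation was called by camera (adjusted p = 7.83e-17) with 0 other lists. Genes and regions were drawn independently of each other in these simulations. They therefore leave out the correlation between genes (estimated median 0.310 over the lists) and cannot show false calls that arise from it. Alternatives were other normalizations and filters, DESeq2 1.42.0, limma-trend on log2(TPM + 1), limma-voom with sample weights, fits on 2 groups, the replicate number as a block, leaving out each library, and, added after seeing the data, the library's length slope as a covariate, leaving out the 2 libraries with the lowest slope, and all alternatives of the 5hmC test except merging regions and leaving out chromosomes X and Y. The length slope is the trend of a library's gene levels with gene length. It ran from -0.40 in het control replicate 1 and -0.32 in wild-type control replicate 1 to 0.30 in wild-type control replicate 3 and 0.32 in wild-type stressed replicate 3. Its correlation with the first principal component (48.2% of the variance) was 0.991 across the 12 libraries, and it did not separate stressed from control (exact permutation p = 0.446) or het from wild-type mice (0.855). Fits without the 2 libraries of lowest slope keep 2 mice in each control group.

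For the test of chromosome 6 described in the closing part, a first version used other bounds for 5hmC than for RNA; the same rule was then applied to both after the shares had been seen. In controls the 5hmC value met both the condition for and the condition against linked DNA, so it is left open. The result in stressed mice was the same under either version.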

Results

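RNA and the DNA mark 5-hydroxymethylcytosine (5hmC) were profiled in the striatum of 12 female C57BL/6 mice. The mice were wild type or heterozygous (het) for Cntnap2, which encodes the neuronal adhesion protein Caspr2, and their mothers had either been exposed to 7 days of variable stress from embryonic day 12.5 or not been stressed. Each of the 4 groups held 3 mice, and each mouse gave 1 RNA library and 1 library of 5hmC-enriched DNA, per the labels. For het control replicate 1 the RNA data carry another animal number than the label and the 5hmC tables, so whether both came from the same mouse is unsure. The RNA libraries held 13587154 to 24039706 expected counts over 37289 genes, of which 15955 were tested. All het libraries were deeper (21410135 to 24039706) than all wild-type libraries (13587154 to 18538304). Depth thus goes with genotype in the RNA comparisons of het with wild-type mice. It was scaled by TMM but not tested as a cause. The 5hmC counts cover the regions of each of 5 comparison tables, with 24982 to 38107 regions per table.

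Cntnap2 RNA was close to equal in the 2 genotypes when measured as TPM and lower in het mice, without passing the test, when measured as counts. Its level was 46.4 ± 7.78 TPM in het mice and 48.2 ± 11.3 TPM in wild-type mice (SD, n = 6 each), a difference of -0.04 in log2(TPM + 1) (two-sided exact permutation p = 0.814). The quasi-likelihood test of edgeR on counts gave a log2 fold change of -0.38 ± 0.16 (SE) for the genotype average, with an adjusted p of 0.9999. Per condition edgeR gave -0.36 ± 0.22 in controls and -0.40 ± 0.22 in stressed mice (adjusted p = 0.99999 and 0.99992). The 6983-nucleotide transcript ENSMUST00000114641.1 was at 5.72 ± 2.05 TPM in het and 11.4 ± 7.73 TPM in wild-type mice (exact permutation p = 0.134, adjusted p = 0.386 over 3 transcripts). Wild-type stressed replicate 3 and wild-type control replicate 3, which have the highest length slopes, were at 22.86 and 19.49 TPM. The other wild-type libraries were at 4.12 to 7.5 TPM and the het libraries at 1.89 to 7.46 TPM. The 1625-nucleotide transcript ENSMUST00000060839.6 was at 38.9 ± 7.03 and 34.8 ± 3.61 TPM (exact permutation p = 0.258, adjusted p = 0.386). The small TPM difference turned positive without wild-type stressed replicate 3 (0.06), het control replicate 2 (0.03) or wild-type control replicate 3 (0.00198). The edgeR value stayed negative in all 12 fits that left out 1 library (-0.44 to -0.26). With all libraries the genotype average had an unadjusted p under 0.05, and in stressed mice the CPM of the 2 genotypes did not overlap, which chance gives in 10% of genes. With both libraries of lowest length slope left out and the slope as a covariate, choices made after seeing the data, the edgeR value was -0.41 with an adjusted p of 0.00280. That fit keeps 2 controls of each genotype.

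**Figure D1:**
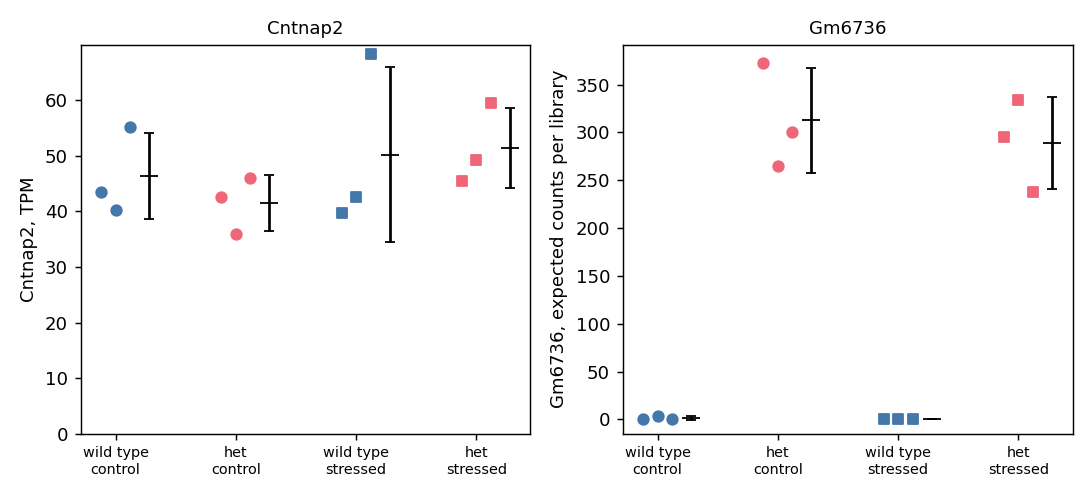
Cntnap2 in TPM (left) and Gm6736 in expected counts (right) for each library, with the 4 groups of 3 mice on the horizontal axis; circles are controls, squares stressed mice, blue wild type, red het, bars mean and SD. Cntnap2 overlaps between genotypes, while Gm6736 lies between 238 and 373 counts in the 6 het libraries and at 0 to 4 counts in the 6 wild-type libraries. The counts are not scaled for library depth, which was higher in all het than in all wild-type libraries.

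The comparison of het with wild-type mice without prenatal stress asks what the Cntnap2 genotype alone changes. The pseudogene Gm6736 rose in het mice: its 3 libraries held 265 to 373 counts and 13.9 ± 0.888 TPM (SD, n = 3), against 4 counts in 1 wild-type library and 0 in the others. That is a ratio of 184 (95% counting interval 71.5 to 676), and edgeR's quasi-likelihood test gave an adjusted p of 0.0110. Among gene groups, oligodendrocyte genes, which build myelin, were lower as a list, with 19 of 20 members lower and a median log2 fold change of -0.27 (camera adjusted p = 4.80e-10; adjusted p = 0.638 with an estimated correlation). The 10 thalamus markers were all lower, median -0.50 (adjusted p = 1.37e-05; adjusted p = 0.638 with an estimated correlation). Genes shared by medium spiny neurons, the main cells of the striatum, were higher in 24 of 24 members, median 0.19 (adjusted p = 0.00168; adjusted p = 0.828 with an estimated correlation). Activity-regulated immediate early genes were higher in 24 of 26, median 0.20 (adjusted p = 0.00117; adjusted p = 0.673 with an estimated correlation). Heat shock and unfolded protein genes were lower in 20 of 22 (adjusted p = 0.000296; adjusted p = 0.673 with an estimated correlation). Markers of septum, pallidum and basal forebrain were lower in 10 of 12 (adjusted p = 0.00603; adjusted p = 0.673 with an estimated correlation). Stress axis genes were called lower, with 10 of 19 lower (adjusted p = 0.0297; adjusted p = 0.673 with an estimated correlation). Ribosomal protein genes were higher in 41 of 43 (adjusted p = 0.0161; adjusted p = 0.957 with an estimated correlation), but the list was called lower without het control replicate 1 (mean -0.30, adjusted p = 0.0490) or wild-type control replicate 3 (-0.18, 0.00102). The heat shock list was not called without wild-type control replicate 1 (adjusted p = 0.0918) or het control replicate 3 (0.430), nor the septum list without het control replicates 1 (0.169) or 2 (0.0819) or wild-type control replicate 3 (0.309). The stress axis list was not called without wild-type control replicates 1 (0.0971) or 2 (0.191) or het control replicates 2 (0.993) or 3 (0.211).

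No member of these lists passed over all genes by edgeR. For this comparison DESeq2 and limma-trend called 2 genes each and limma-voom with sample weights 988, among them Prkcd (adjusted p = 0.0432) and Ugt8a (0.0228), both lower. Of the immediate early list it called Bdnf (-2.44, adjusted p = 0.0282) and Nr4a2 (-2.77, 0.0428) lower, against the list, and Egr3 (0.57, 0.0486) higher. Of the septum list it called Onecut2 higher, against that list (1.12, adjusted p = 0.0411). Of the stress axis list it called Avpr1a, Crhr1, Htr1a (-1.57, adjusted p = 0.00867) and Htr2a (-0.61, 0.0254) lower, as it did Bdnf. A further edgeR fit, chosen after seeing the data, used the length slope as a covariate. It left out the 2 libraries of lowest slope, het and wild-type control replicates 1, so 2 mice faced 2. It called 203 genes, among them Bdnf (-1.78, adjusted p = 0.0344) and Htr1a (-1.19, 0.0467), again lower. Cntnap2 (-0.44, adjusted p = 0.0215) and Ugt8a (-0.47, 0.0368) were also called lower in that fit. Both it and limma-voom called the shared spiny neuron genes Actn2, Adcy5, Ppp1r1b, Rasd2, Rasgrp2 and Sez6 higher, with their list. Adjusted over the list alone, Prkcd, a protein kinase C of thalamic neurons, passed with -1.82 ± 0.49 (adjusted p = 0.0362), while the thalamus marker Ramp3 (-0.98), the myelin genes Mal (-0.28) and Ermn (-0.40), the immediate early genes Junb (0.41) and Nptx2 (0.40), and the spiny neuron genes Rxrg (0.30) and Arpp21 (0.22) did not. Of the genes with the smallest p that did not pass by edgeR, Gm10800 (5.00), 2810408I11Rik (1.49), ENSMUSG00000087580.2 (2.59), Gm15895 (0.90) and B3gnt4 (1.47) had higher values in het mice. Rab37, a vesicle-trafficking GTPase (-1.31), the transcription factor Shox2 (-3.52), the oxysterol hydroxylase Cyp39a1 (-0.82), the potassium channel subunit Kcns3 (-0.79) and the phosphatase Dusp10 (-0.64) had lower values. Of these, limma-voom with sample weights called all but B3gnt4 and Shox2, and DESeq2 and limma-trend called Gm10800. Both groups of 3 did not overlap for 540 genes, 3.38% of those tested, where chance gives 10%. The Gm6736 call ended without het stressed replicates 1, 2 or 3 (adjusted p = 0.0722, 0.0637 and 0.0630), without het control replicate 2 (0.0598), and in a fit on these groups only (0.516). Without wild-type control replicate 3 the thalamus list was not called (adjusted p = 0.230). The immediate early list was lost without wild-type control replicate 1 (0.225) or het control replicate 2 (0.280), and the spiny neuron list without either of these (0.175 and 0.890) or het control replicate 3 (0.536). The 8 lists called became 14 without wild-type control replicate 1, 19 without het control replicate 1 and 13 without het control replicate 3.

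Between het and wild-type mice after prenatal stress, Gm6736 again rose in het mice, with 238 to 334 counts per library against 0 in all 3 wild-type libraries. It was at least 170-fold higher by the 95% counting limit, with a ratio of 209 to a floor of 3 counts over the wild-type group (edgeR adjusted p = 0.00875). Immature neuron and neurogenesis genes were lower in 17 of 19 members, with a median log2 fold change of -0.46 (camera adjusted p = 1.05e-16), and this call held with an estimated correlation (adjusted p = 0.00404), but fry gave an adjusted p of 0.0542. Its members with the smallest p were the progenitor transcription factors Sox11 (-0.71 ± 0.24) and Sox4 (-0.33 ± 0.12), neither of which passed by edgeR over all genes or adjusted over the list alone. The immature neuron mean was 0.38 and 0.44 in wild-type stressed replicates 2 and 3, but -0.0016 in replicate 1. In stressed het mice it was -0.24 to -0.02. Wild-type stressed replicate 2 is the animal with almost no Xist described in the closing part. The call with an estimated correlation was not repeated without it. Ependymal genes of motile cilia were lower in 11 of 11 members, median -0.72 (adjusted p = 1.14e-08; adjusted p = 0.608 with an estimated correlation), with Dnah11 at -1.57 and Ak7 at -1.05. Oligodendrocyte genes were higher in 19 of 20, median 0.18 (adjusted p = 1.41e-06; adjusted p = 0.608 with an estimated correlation), with Aspa at 0.36 and Ugt8a at 0.22. Immediate early genes were higher in 22 of 26, median 0.26 (adjusted p = 9.98e-05; adjusted p = 0.608 with an estimated correlation), with Dusp6 at 0.38 and Dusp1 at 0.29, but not without het stressed replicate 3 (adjusted p = 0.102). Astrocyte genes were higher in 15 of 16 (adjusted p = 0.000566; adjusted p = 0.278 with an estimated correlation), but not without wild-type stressed replicate 1 (adjusted p = 0.153). Mitochondrially encoded genes were lower in 12 of 13 (adjusted p = 0.00115; adjusted p = 0.984 with an estimated correlation), but not without wild-type stressed replicates 2 (adjusted p = 0.0512) or 3 (0.0791).

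Choroid plexus genes were higher in 12 of 14 members, median 1.89 (camera adjusted p = 0.0401; adjusted p = 0.984 with an estimated correlation), led by the thyroxine carrier Ttr (5.25 ± 2.06) and the potassium channel subunit Kcne2 (5.90 ± 2.60), which did not pass. This list has no stable direction. Without het stressed replicate 3 its mean was -0.85 and it was called lower (adjusted p = 0.0319). It was not called without wild-type stressed replicates 1 (0.643) or 2 (0.215), wild-type control replicates 1 (0.0770), 2 (0.0817) or 3 (0.0610), or het control replicate 1 (0.0654). DESeq2 called 3 genes, limma-trend 2 and limma-voom with sample weights 3. The other genes named by the rule did not pass by edgeR: Gm10800 (3.82), ENSMUSG00000091663.1 (0.54), Abcg3 (1.07), Gm15764 (1.80) and ENSMUSG00000075319.2 (3.76) had higher values, and Gm11175 (-0.80), Fam129c (-0.74), A530084C06Rik (-1.27), Slc16a8 (-1.17) and Amd-ps3 (-5.11) lower values. DESeq2 (adjusted p = 0.0200) and limma-trend (0.0137) called Gm10800, and limma-voom with sample weights called Gm11175 (0.0349). The Gm6736 call ended without het stressed replicates 1, 2 or 3 (adjusted p = 0.0695, 0.0655 and 0.0558) or wild-type stressed replicate 2 (0.0526). The 7 lists called became 11 without wild-type stressed replicate 2 and 16 without wild-type stressed replicate 3.

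Averaged over both prenatal conditions, Gm6736 was the 1 gene that edgeR called by genotype (log2 fold change 9.20 ± 0.51, adjusted p = 0.000520), higher in 6 of 6 het mice, and it was called in each of the 12 fits that left out 1 library. DESeq2 called 3 genes, limma-trend 2 and limma-voom with sample weights 10, and edgeR called 4 with the length slope as a covariate and 8 with the slope and without the 2 libraries of lowest slope. A second gene, Atp6v0c-ps2, was called without het control replicate 3 (-4.69, adjusted p = 0.00999), where 2 genes passed; with all libraries it was at -2.09. Gm10800 held 23 to 46 counts in the het libraries and at most 4 in any wild-type library, and its log2 fold change of 4.41 did not pass by edgeR (adjusted p = 0.119). It was called without a filter (adjusted p = 0.0422), by DESeq2 (2.99e-09), limma-trend (0.000161) and limma-voom with sample weights (0.000127), and with the length slope as a covariate (0.00846), the last chosen after seeing the data. DESeq2 and limma-trend also called Gm10800 in each pairwise genotype comparison. In total, 12 genes separated all het from all wild-type libraries, where chance gives 34.5. Immature neuron genes were lower in 17 of 19 members, median -0.19 (camera adjusted p = 4.43e-08; adjusted p = 0.0466 with an estimated correlation), with Sox11 at -0.45 and the interneuron progenitor factor Dlx2 at -0.31. In controls alone, 8 immature neuron genes were higher and 11 lower (adjusted p = 0.912). Immediate early genes were higher in 24 of 26, median 0.21 (adjusted p = 4.43e-08; adjusted p = 0.516 with an estimated correlation), with Junb at 0.35 and Dusp1 at 0.27. Ependymal genes, among them Hydin (-0.91) and Dnah11 (-1.01), were lower in 11 of 11, median -0.55 (adjusted p = 5.63e-06; adjusted p = 0.779 with an estimated correlation). Thalamus markers, with Prkcd at -1.01 and the vesicular glutamate transporter Slc17a6 at -0.74, were lower in 10 of 10, median -0.27 (adjusted p = 0.000255; adjusted p = 0.775 with an estimated correlation). Markers of septum, pallidum and basal forebrain were lower in 12 of 12 (adjusted p = 0.00148; adjusted p = 0.779 with an estimated correlation), but not without wild-type stressed replicate 3 (adjusted p = 0.354) or wild-type control replicate 3 (0.191). Heat shock genes were lower in 20 of 22 (adjusted p = 0.0189; adjusted p = 0.932 with an estimated correlation), but not without het stressed replicate 1 (adjusted p = 0.254), wild-type stressed replicates 1 (0.0519) or 3 (0.334), wild-type control replicates 1 (0.243) or 2 (0.212) or het control replicate 3 (0.732). Without wild-type control replicate 1 the ependymal list was not called (adjusted p = 0.243), nor the thalamus list without wild-type control replicate 3 (0.356). The 6 lists called became 10 to 19 without wild-type stressed replicate 2 (10) or 3 (14), wild-type control replicate 1 (14) or 3 (10), or het control replicate 1 (19) or 3 (10).

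The comparison of stressed with unstressed wild-type mice asks what prenatal stress changes on its own. Oligodendrocyte genes were lower in 20 of 20 members, with a median log2 fold change of -0.46 (camera adjusted p = 6.96e-19; adjusted p = 0.149 with an estimated correlation). Adjusted over the list alone, 9 of the 20 fell, among them Ugt8a, which makes myelin galactolipids (-0.61 ± 0.15, adjusted p = 0.0169), and the gap junction gene Gjb1 (-0.75 ± 0.18, adjusted p = 0.0169). Over all genes none passed by edgeR, while DESeq2 called Mal (adjusted p = 0.00657) and Ugt8a (0.0486), and limma-voom with sample weights called both (0.0464 and 0.0203), Ermn (0.0323) and Trf (0.0344). An edgeR fit chosen after seeing the data, with the length slope as a covariate and without the 2 libraries of lowest slope, called 4 genes, among them Ugt8a (-0.74, adjusted p = 0.0229) and Trf (-0.74, 0.0302). That fit keeps 2 wild-type controls. Immature neuron genes were higher in 15 of 19, median 0.31 (adjusted p = 2.55e-06; adjusted p = 0.1196 with an estimated correlation). Sox11 (0.93 ± 0.24) and Sox4 (0.43 ± 0.12) rose when adjusted over the list alone (adjusted p = 0.0424 for both). Over all genes they did not pass by edgeR, and limma-voom with sample weights called Sox11 (adjusted p = 0.0447). The immature neuron mean was 0.38 and 0.44 in wild-type stressed replicates 2 and 3. In replicate 1 it was -0.0016, within the range of the wild-type controls (-0.15 to 0.07). Wild-type stressed replicate 2 is the animal with almost no Xist described in the closing part.

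Choroid plexus genes were lower in these stressed mice in 14 of 14 members, median -3.04 (camera adjusted p = 6.58e-13, or 0.378 with an estimated correlation). In replicates 1, 2 and 3 the list mean was -1.63, -1.40 and -0.91 for stressed mice and 1.81, 0.81 and 1.02 for controls. A different share of choroid plexus in the punches was not tested as a cause, so these values do not show a response of the striatum itself. Ttr was at 4.87 ± 5.73 TPM in stressed and 388 ± 146 TPM in unstressed wild-type mice (SD, n = 3 each); its log2 fold change of -6.59 and that of the tight junction gene Cldn2 (-4.42) did not pass by edgeR. Interferon and inflammation genes were lower in 17 of 17, median -0.60 (adjusted p = 1.44e-09; adjusted p = 0.378 with an estimated correlation), with Ifit1 at -1.07. Markers of other cells were lower with them: microglia in 17 of 17 (adjusted p = 0.00119; adjusted p = 0.378 with an estimated correlation), fibroblasts and meninges in 11 of 13 (0.000397; adjusted p = 0.378 with an estimated correlation) and blood in 6 of 6 (0.0167; adjusted p = 0.715 with an estimated correlation). The microglia list was not called without wild-type stressed replicate 3 (adjusted p = 0.152) or wild-type control replicate 1 (0.135), nor the fibroblast list without wild-type control replicate 3 (0.0880). The blood list was not called without wild-type stressed replicate 1 (0.0627) or 3 (0.636) or wild-type control replicate 1 (0.575). Thalamus markers were lower in 9 of 10, median -0.46 (adjusted p = 0.00193; adjusted p = 0.454 with an estimated correlation). Adjusted over the list alone, Ramp3 fell (-1.36 ± 0.38, adjusted p = 0.0422), and Prkcd was at -1.47. No thalamus member passed over all genes by edgeR, and the list was not called without wild-type control replicate 3 (adjusted p = 0.723).

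No single gene passed between stressed and unstressed wild-type mice by edgeR, with 397 genes at an unadjusted p under 0.05; DESeq2 called 11, all lower, limma-trend 0 and limma-voom with sample weights 43. The genes with the smallest p were lower for Rab37 (-1.66), Enpp2, which makes the lipid signal lysophosphatidic acid (-0.999), Klhl4 (-0.58), Shox2 (-4.52) and ENSMUSG00000091663.1 (-0.72), and higher for Fam129c (0.76), Sox1ot (0.66), Tox3 (0.86), Sox11 (0.93) and Gpr135 (0.55). DESeq2 called all 5 of the lower ones, and limma-voom with sample weights called Enpp2, Klhl4, ENSMUSG00000091663.1, Sox1ot and Sox11. Without wild-type control replicate 3 edgeR called 1 gene, Rpsa-ps10 (adjusted p = 0.0286). The 17 lists called became 11 without wild-type control replicate 1.

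**Figure D2:**
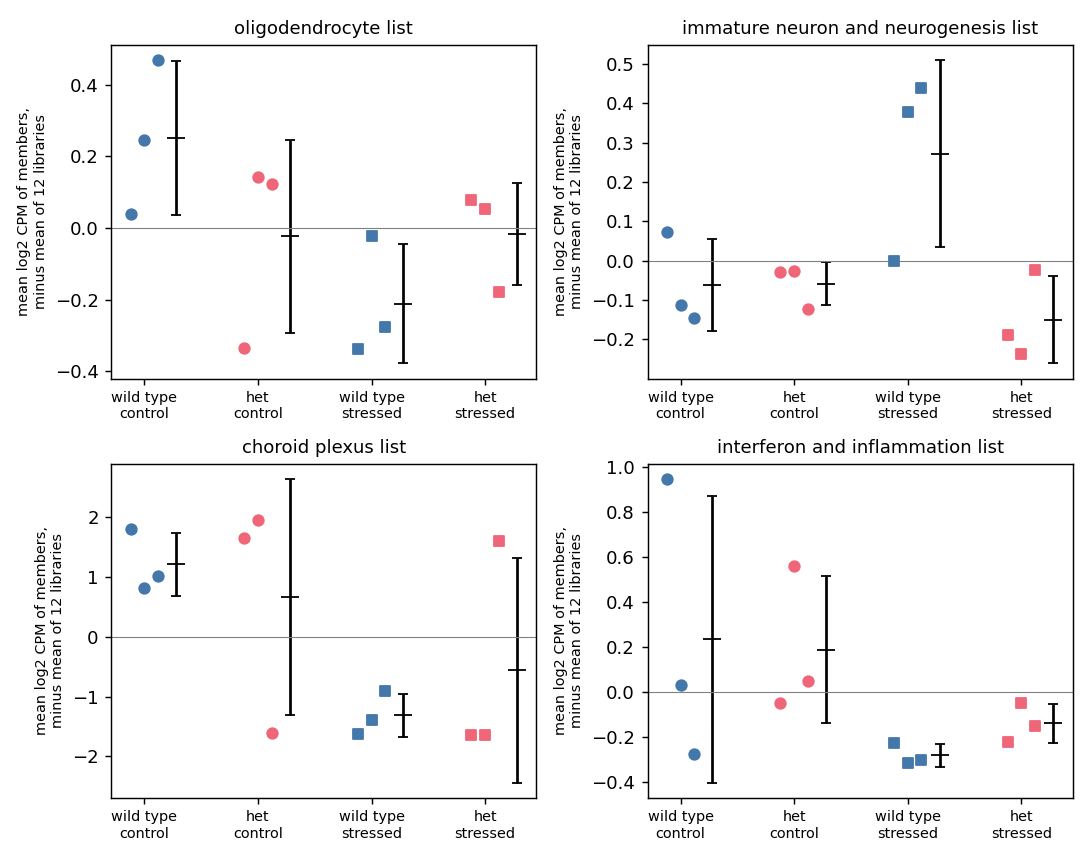
Mean log2 CPM of the members of 4 gene lists in each library, as the difference from the mean of the 12 libraries (vertical axis), for the 4 groups of 3 mice; circles are controls, squares stressed mice, blue wild type and red het, and the bars give mean and SD. The oligodendrocyte mean is 0.25 in wild-type controls and -0.21 in wild-type stressed mice, and the choroid plexus means of the het groups hold single libraries at -1.61 (het control) and 1.61 (het stressed) that lie apart from the other libraries of their group.

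In het mice, prenatal stress was followed by lower choroid plexus genes in 14 of 14 members, median log2 fold change -1.14 (camera adjusted p = 1.50e-06; adjusted p = 0.625 with an estimated correlation), with Otx2 at -1.21 and Sostdc1 at -1.01. In replicates 1, 2 and 3 the list mean was 1.65, 1.95 and -1.61 for het controls. For het stressed mice it was -1.64, -1.65 and 1.61, so a single library of each group went the other way. Ependymal genes were lower in 11 of 11, median -0.71 (adjusted p = 3.58e-07; adjusted p = 0.625 with an estimated correlation), with Dynlrb2 at -1.08 and Mia at -1.40. Interferon and inflammation genes were lower in 16 of 17, median -0.35 (adjusted p = 6.62e-06; adjusted p = 0.625 with an estimated correlation), with the antigen presentation genes B2m at -0.34 and H2-D1 at -0.35. Markers of blood were lower with them in 6 of 6 (adjusted p = 0.00644; adjusted p = 0.625 with an estimated correlation), of endothelium and mural cells in 18 of 20 (0.0372; adjusted p = 0.707 with an estimated correlation) and of fibroblasts and meninges in 10 of 13 (0.0190; adjusted p = 0.625 with an estimated correlation). Stress axis receptors and peptides were higher in 15 of 19, median 0.15 (adjusted p = 1.67e-05; adjusted p = 0.625 with an estimated correlation). In that list the serotonin receptor Htr2a rose when adjusted over the list alone (0.87 ± 0.18, adjusted p = 0.00994; 7.42 ± 0.817 against 3.51 ± 0.980 TPM, SD, n = 3 each), and Htr1a was at 0.72. None passed over all genes by edgeR, and limma-voom with sample weights called Htr2a and Htr1a (adjusted p = 0.0462 for both). The same tool called both lower in het than in wild-type controls (Htr2a -0.61, adjusted p = 0.0254, and Htr1a -1.57, 0.00867). A low level in the het controls is thus not told apart from a rise with stress. Cortical excitatory neuron markers, from tissue next to the striatum, were also higher in stressed het mice, in 12 of 15 members, median 0.47 (adjusted p = 0.00644; adjusted p = 0.625 with an estimated correlation). Without het control replicate 2 the choroid plexus (adjusted p = 0.0569), interferon (0.0857) and stress axis lists (0.0603) were not called, nor were the blood (0.0569), endothelium (0.145) and fibroblast lists (0.0603). The blood list was also not called without het control replicate 1 (adjusted p = 0.433), and the fibroblast list without het control replicate 1 (0.383) or het stressed replicate 2 (0.210) or 3 (0.236). The endothelium list was not called without het stressed replicate 2 (adjusted p = 0.104) or 3 (0.400) or wild-type stressed replicate 3 (0.0525), and its mean reversed without het control replicate 3 (adjusted p = 0.924). The cortical list was not called without het stressed replicate 2 (adjusted p = 0.0819) or het control replicate 3 (0.314).

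Synaptic scaffold genes were also higher in stressed het mice, in 33 of 37 members, median 0.23 (camera adjusted p = 6.20e-07; adjusted p = 0.625 with an estimated correlation), with Homer2 at 0.53 and the vesicle protein Sv2b at 0.40. Cytosolic ribosomal protein genes were lower in 43 of 43, median -0.38 (adjusted p = 3.58e-07; adjusted p = 0.687 with an estimated correlation), with Rps29 at -0.34 and Rpl37 at -0.39, but the list mean was 0.03 without het control replicate 1 (adjusted p = 0.951), where the scaffold list was not called either (0.433). No gene passed by edgeR, with 179 at an unadjusted p under 0.05; DESeq2 and limma-trend called 0 and limma-voom with sample weights 14. The edgeR fit chosen after seeing the data had the length slope as a covariate and left out the 2 libraries of lowest slope. With 2 het controls kept, it called 38 genes. Among them were the cortical markers Neurod2 (1.64, adjusted p = 0.00810), Tbr1 (1.78, 0.00810), Neurod6 (2.31, 0.0209), Nrn1 (1.95, 0.0257) and Slc17a7 (2.33, 0.0298), all higher, and Rspo1 of the same list, lower (-0.95, 0.0466). The stress axis genes Bdnf (2.15, adjusted p = 0.0189) and Htr1a (1.31, 0.0458) were higher with them. Htr2a (0.87), Sgcd (1.37), Ndst4 (1.28), Fgf2 (1.62) and Epha5 (0.56) had the smallest p among higher values, and the lactate transporter Slc16a8 (-1.82), Gstm2 (-1.05), Fscn2 (-1.44), Clec4a2 (-0.96) and Rspo1 (-0.75) among lower values. Of these, limma-voom with sample weights called Htr2a, Slc16a8 and Rspo1. The 17 lists called became 10 without het control replicate 2.

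Averaged over genotypes, prenatal stress was followed by lower choroid plexus genes (14 of 14, median log2 fold change -1.96, camera adjusted p = 5.71e-14; adjusted p = 0.327 with an estimated correlation). The mean of that list ran from -1.65 to 1.61 in stressed libraries and from -1.61 to 1.95 in control libraries. A different share of choroid plexus in the punches was not tested as a cause in any comparison. Interferon and inflammation genes were lower in 17 of 17, median -0.43 (adjusted p = 2.07e-11; adjusted p = 0.327 with an estimated correlation). Oligodendrocyte genes were lower in 20 of 20, median -0.23 (adjusted p = 1.16e-10; adjusted p = 0.327 with an estimated correlation). In het mice alone, 9 oligodendrocyte genes were higher and 11 lower with stress (median -0.01, adjusted p = 0.619). Ugt8a (-0.38) and Gjb1 (-0.48) fell when adjusted over the list alone (adjusted p = 0.0389 for both), 2 of the 20 oligodendrocyte genes. Ttr (-4.09), Cldn2 (-2.87), B2m (-0.32) and H2-D1 (-0.38) did not pass in either way by edgeR. Stress axis genes were higher in 15 of 19, median 0.17 (adjusted p = 0.000469; adjusted p = 0.327 with an estimated correlation); Htr2a rose when adjusted over the list alone (0.61 ± 0.13, adjusted p = 0.0111), and the oxytocin receptor Oxtr was at 0.66. Synaptic scaffold genes were higher in 32 of 37, median 0.19 (adjusted p = 2.19e-07; adjusted p = 0.488 with an estimated correlation), with Homer2 at 0.51 and Nptxr at 0.48.

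None of these genes passed over all genes by edgeR, which called 0 for the stress average, with 374 at an unadjusted p under 0.05, DESeq2 and limma-trend called 0, and limma-voom with sample weights 6. Lower values with the smallest p were those of Clic3 (-1.25), Slc16a8 (-1.18), Gstm2 (-0.81), Enpp2 (-0.69) and Depdc7 (-0.76), and higher values those of Htr2a (0.61), Sgcd (1.20), the calcium pump Atp2b4 (0.76), Sox11 (0.68) and Mmab (0.29). Of these, limma-voom with sample weights called Clic3, Enpp2 and Depdc7. Across genes, which are not independent replicates, the stress log2 fold changes in wild-type and het mice correlated with Pearson r = 0.178 and Spearman rho = 0.330, and 87 of 100 regroupings within genotype gave a Pearson correlation as large. The genotype changes in control and stressed mice correlated with r = -0.0227 and rho = -0.0665, with 98 of 100 regroupings as large.

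The interaction asks whether prenatal stress acts differently in het and wild-type mice. Relative to wild type, the stress difference in het mice was higher for oligodendrocyte genes in 20 of 20 members, median 0.47 (camera adjusted p = 4.50e-14; adjusted p = 0.201 with an estimated correlation), with Mal at 0.43 and Ugt8a at 0.48. It was lower for immature neuron genes in 17 of 19, median -0.47 (adjusted p = 1.36e-07; adjusted p = 0.0598 with an estimated correlation), with Sox4 at -0.47 and the proliferation marker Mki67 at -1.54. Astrocyte genes were higher in 14 of 16, median 0.16 (adjusted p = 0.000791; adjusted p = 0.201 with an estimated correlation), with Gfap at 0.97 and Gjb6 at 0.39. Thalamus markers were higher in 9 of 10, median 0.48 (adjusted p = 0.00271; adjusted p = 0.842 with an estimated correlation), with Ramp3 at 1.33 and Prkcd at 1.62, but not without het control replicate 1 (adjusted p = 0.113) or wild-type control replicate 3 (0.361). Choroid plexus genes were higher in 13 of 14, median 1.95 (adjusted p = 0.0112; adjusted p = 0.842 with an estimated correlation), with Ttr at 4.99 and Kcne2 at 5.63, but the list mean was -0.91 without het stressed replicate 3 (adjusted p = 0.737). That list was also not called without het control replicate 3 (adjusted p = 0.756), wild-type stressed replicates 1 (0.210) or 2 (0.112), or wild-type control replicate 1 (0.220).

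No gene passed the interaction test by edgeR, over all genes or adjusted over a list alone; 212 had an unadjusted p under 0.05, and DESeq2, limma-trend and limma-voom with sample weights each called 0. With the length slope as a covariate and without the 2 libraries of lowest slope, edgeR called 84 genes, among them Ugt8a (0.68, adjusted p = 0.0383), Gm11175 (-1.08, 0.0338) and, against the direction of the immature neuron list, Stmn2 (0.85, 0.0468). That fit, chosen after seeing the data, keeps 2 controls of each genotype. The secreted phosphoprotein Spp1 (2.11), Rab37 (1.80), Gm7488 (1.49), Shox2 (5.07) and Abcg3 (1.51) had the smallest p among positive values, and Fam129c (-1.19), Gm11175 (-0.94), Xrra1 (-1.26), Fscn2 (-1.58) and Oaz1-ps (-11.67) among negative ones. The 12 lists called became 5 without wild-type stressed replicate 2, the animal with almost no Xist described in the closing part.

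Stressed het mice, which carry both factors, were also compared with unstressed wild-type mice. Gm6736 rose (edgeR adjusted p = 0.0133), and oligodendrocyte genes were lower in 20 of 20 members, median log2 fold change -0.31 (camera adjusted p = 9.78e-11; adjusted p = 0.425 with an estimated correlation), with Gjb1 at -0.56 and Ugt8a at -0.40. Ependymal genes were lower in 11 of 11, median -1.16 (adjusted p = 1.12e-09; adjusted p = 0.425 with an estimated correlation), with the cilia regulator Foxj1 at -0.78 and Dynlrb2 at -1.42. Choroid plexus genes were lower in 14 of 14, median -1.21 (adjusted p = 1.19e-10; adjusted p = 0.425 with an estimated correlation), with Otx2 at -1.46 and Cldn2 at -1.44. The list mean of het stressed replicate 3 (1.61) lay within the range of the wild-type controls (0.81 to 1.81). Interferon genes were lower in 17 of 17, median -0.52 (adjusted p = 1.50e-07; adjusted p = 0.425 with an estimated correlation), with B2m at -0.32 and the complement gene C3 at -1.26, but not without wild-type control replicate 1 (adjusted p = 0.491). No list member passed by edgeR over all genes or adjusted over the list alone, and limma-voom with sample weights called Ugt8a over all genes (adjusted p = 0.0365). DESeq2 called 3 genes, limma-trend 2 and limma-voom with sample weights 50. Genes with the smallest p that did not pass by edgeR were higher for Gm10800 (4.29), 4931422A03Rik (2.01), G530011O06Rik (1.21), Ndst4 (1.33) and Ccdc116 (0.83), and lower for Slc16a8 (-1.71), Tmem35b (-1.45), Kcns3 (-0.81), Rab37 (-1.17) and Gstm2 (-0.88). Of these, all 3 other tools called Gm10800, and limma-voom with sample weights also called G530011O06Rik, Tmem35b, Kcns3 and Slc16a8. The Gm6736 call ended without het stressed replicates 1, 2 or 3 (adjusted p = 0.106, 0.101 and 0.0836), wild-type control replicate 1 (0.0533), or het control replicates 2 (0.0640) or 3 (0.0501), and in a fit on these groups only (0.0955). The 21 lists called became 7 without wild-type control replicate 1.

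For 5hmC, the region that changed in the genotype comparison without stress lay on chromosome 6, from 34450938 to 34451949 in mm9. Its level fell in het mice, from 30.0 ± 5.76 to 14.9 ± 3.24 CPM (SD, n = 3 each; log2 fold change -1.07 ± 0.18, edgeR adjusted p = 0.00271). It was also lower in stressed het mice than in unstressed wild-type mice, at 20.2 ± 3.38 against 34.4 ± 6.78 CPM (-0.85, adjusted p = 0.0412), but both comparisons share the 3 wild-type control libraries. The region is not in the table of stressed het and stressed wild-type mice, and between stressed and unstressed wild-type mice it differed by -0.05 (adjusted p = 0.955). It was the 1 edgeR call among 38107 regions. Alternatives added after seeing the data gave 32 with the replicate number as a block, this region among them. By limma-voom with sample weights there were 5 and by DESeq2 0, also added then. Of all regions, 2863 had an unadjusted p under 0.05, 1389 higher and 1474 lower. In controls, DESeq2 did not call it (adjusted p = 0.398), and it was not called without het control replicate 3 (0.182) or wild-type control replicate 3 (0.391); the count of calls was 3 without het control replicate 1, 2 without het control replicate 2 and 7 without wild-type control replicate 2. Regions that did not pass were higher on chromosome 10 at 60470500 (0.88, adjusted p = 0.0927), chromosome 4 at 42086400 (0.57) and chromosome 14 at 104215500 (0.70), and lower on chromosome 5 at 50358700 (-0.60) and chromosome 4 at 48275295 (-0.58).

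**Figure D3:**
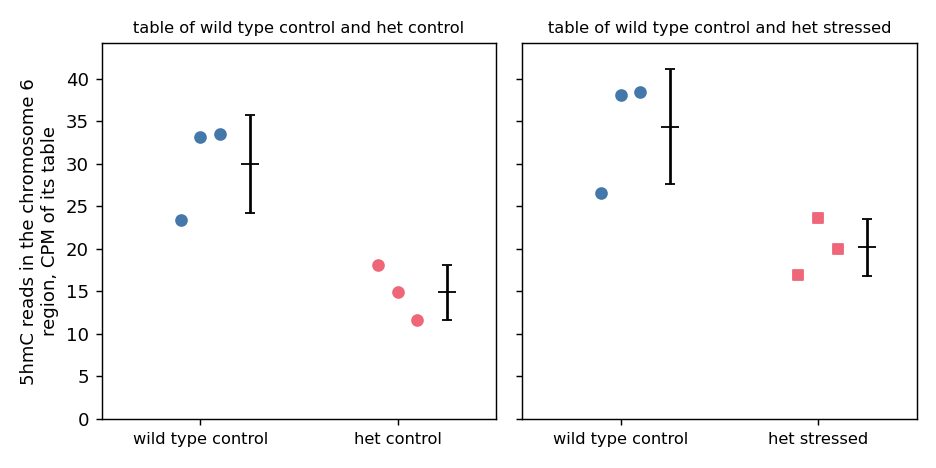
5hmC level of the chromosome 6 region that starts at 34450938, in CPM within its table (vertical axis), for each library of the table of wild-type and het controls (left) and of wild-type controls and stressed het mice (right); bars give mean and SD of 3 mice. The het means are 14.9 and 20.2 CPM and the wild-type means 30.0 and 34.4 CPM.

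Between stressed het and stressed wild-type mice, edgeR called 0 of 24982 regions, with 1852 at an unadjusted p under 0.05, DESeq2 called 0 and limma-voom with sample weights 0. The regions with the smallest p were lower on chromosome 6 from 47727622 to 47728670 (-1.01), chromosome 8 at 117107978 (-0.80) and chromosome 3 at 156316774 (-0.995), and higher on chromosome 3 at 40094845 (1.12), chromosome X at 166408132 (0.65) and chromosome 1 at 64618180 (0.89), with a smallest adjusted p of 0.148. The count of calls was 4 without het stressed replicate 1 and 4 without wild-type stressed replicate 1, and the chromosome 6 region passed in both (adjusted p = 0.01001 and 0.00522). The chromosome 3 region at 40094845 (0.00522) and the X region (0.00754) passed without wild-type stressed replicate 1. Wild-type stressed replicate 2, which stayed in that fit, is the animal with almost no Xist described in the closing part. Its median 5hmC deviation over X regions was -0.40. At the X region it was at 42.6 CPM and wild-type stressed replicate 3 at 38.2 CPM. The count was 1 without wild-type stressed replicate 2.

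Prenatal stress in wild-type mice also gave 0 edgeR calls, over 33234 regions with 2941 at an unadjusted p under 0.05; DESeq2 called 0, limma-voom with sample weights 12 and edgeR without robust dispersion 1. The lower regions with the smallest p lay on chromosome 18 at 84445537 (-0.78), chromosome 8 at 81115335 (-0.73) and chromosome 5 at 11477208 (-1.23), and the higher ones on chromosome 10 at 117021399 (0.91) and 118668699 (0.57) and chromosome 5 at 96733769 (0.65). The count was 2 without wild-type stressed replicate 1, where the chromosome 8 region passed (adjusted p = 0.00169). It was 7 without wild-type control replicate 1, where the regions on chromosome 18 (0.00111), chromosome 8 (0.00111) and chromosome 5 at 96733769 (0.0114) passed.

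In het mice, prenatal stress gave 2 of 32205 regions called by edgeR, a count that depends on the processing. It was 15 with regions within 1 kb merged. Alternatives added after seeing the data gave 20 without robust dispersion and 17 with the replicate number as a block. By limma-voom with sample weights there were 15 and by DESeq2 0, also added then. A region on chromosome 11 from 97696925 to 97697931 fell from 24.8 ± 3.35 to 9.89 ± 3.22 CPM (SD, n = 3 each; -1.24, adjusted p = 0.00446), and a region on chromosome 16 from 76796204 to 76797476 rose from 10.3 ± 1.94 to 23.3 ± 5.16 CPM (1.12, adjusted p = 0.0247). These calls rest on few reads. In the chromosome 11 region, replicates 1, 2 and 3 held 33, 9 and 14 reads for stressed het mice and 45, 83 and 52 for het controls. In the chromosome 16 region they held 51, 25 and 45 against 15, 35 and 26. Regions that did not pass were higher on chromosome 3 at 78405890 (1.13) and chromosome 6 at 148576200 (0.87) and lower on chromosome 8 at 124136400 (-0.78) and chromosome 14 at 46144083 (-0.90). The chromosome 11 and 16 regions were not called without het stressed replicate 2 (adjusted p = 0.154 and 0.0939) or 3 (0.248 and 0.413) or het control replicate 2 (0.104 and 0.0742), where no region was. The count was 42 without het stressed replicate 1, 60 without het control replicate 1 and 29 without het control replicate 3. The regions on chromosomes 3 (0.0272) and 8 (0.00602) passed in the first of these fits, all 4 in the second (0.000454 on chromosome 3, 0.00627 on chromosome 6, 0.00222 on chromosome 8 and 0.00346 on chromosome 14), and those on chromosomes 8 (0.0352) and 14 (0.0130) in the third.

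Stressed het against unstressed wild-type mice gave 3 regions of 31667 called by edgeR. The count was 0 without chromosomes X and Y or with regions within 1 kb merged. It was 1 with the replicate number as a block and 6 by limma-voom with sample weights. The 3 regions were the lower one on chromosome 6 described above and 2 higher ones. A region on chromosome X from 166408174 to 166409999 was at 58.4 ± 9.74 against 26.5 ± 12.2 CPM, and a region on chromosome 19 from 37396200 to 37397599 at 38.1 ± 6.70 against 22.1 ± 3.85 CPM (SD, n = 3 each; edgeR adjusted p = 0.0412 for both). Regions that did not pass lay on chromosome 19 at 37040452 (0.78), chromosome 5 at 97454500 (-0.84) and chromosome 12 at 76594599 (-0.60). DESeq2 called 0, as did edgeR without het stressed replicate 2, where the chromosome X, 19 and 6 regions had an adjusted p of 0.405, 0.0875 and 0.0875. The chromosome 6 and 19 regions were also lost without het stressed replicates 1 (0.352 and 0.438) or 3 (0.238 and 0.207, with a count of 1) and wild-type control replicate 3 (0.408 and 0.524). The chromosome 6 and X regions were lost without wild-type control replicate 2 (0.509 and 0.207). The count was 18 without wild-type control replicate 1, where the regions on chromosome 19 at 37040452 (0.0313) and chromosome 5 (0.0115) passed. What genes these regions lie in, and how they relate to RNA, were not analysed here.

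Of the regions in the control genotype table, 44.8% overlapped a region of the stressed genotype table, 16.7 times the mean of 100 rotations along the chromosomes but 0.834 times the overlap of random draws from the union of 45808 regions. For the 2 stress tables, 58.2% overlapped, 17.01 times rotation and 0.842 times the union. Among paired regions the genotype changes had the same sign in 46.3% (Pearson r = -0.126 across regions) and the stress changes in 50.3% (r = 0.0147). Regions are not independent: on mean log2 CPM r was -0.145 for genotype and -0.0369 for stress, and 8 and 71 of 100 groupings of the same libraries gave a correlation as large. At an unadjusted p under 0.05 in both tables, 82 regions were shared for genotype, 20 of them in the same direction, with 60.5 shared if independent, and 149 for stress, 92 in the same direction, with 116 if independent. These counts were not compared with other groupings.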

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

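The interaction test was fixed before the data were examined; the tests of explanations and the fits without doubted libraries were chosen only after the results were seen. By camera, 12 gene lists responded differently to prenatal stress in het and wild-type mice, and none held with an estimated correlation (smallest adjusted p = 0.0598). The stress difference was higher in het mice for oligodendrocyte (adjusted p = 4.50e-14), astrocyte (0.000791), thalamus (0.00271), heat shock and unfolded protein (0.00382), choroid plexus (0.0112), oligodendrocyte precursor (0.0448) and stress axis genes (0.0448). It was lower for immature neuron (1.36e-07), ependyma (0.00575), mitochondrially encoded (0.00575), shared spiny neuron (0.00575) and cytosolic ribosomal protein genes (0.0112). Of 100 splits, 71 gave at least as many lists, the highest other split 20, so chance can account for the number of lists. The count of 12 became 5 without wild-type stressed replicate 2, the animal with almost no Xist described below. For single genes edgeR called 0, with 212 at an unadjusted p under 0.05 and 0 by DESeq2. With the length slope as a covariate and without the 2 libraries of lowest slope it called 84. The splits, 100 of 100 with at least as many and 15 in the highest other, tell nothing here, since any split gives at least 0.

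The oligodendrocyte list leads this set, with members lower in stressed than in unstressed wild-type mice. The list mean was 0.25 in wild-type controls, -0.02 in het controls, -0.02 in stressed het mice and -0.21 in stressed wild-type mice. Het controls were thus also below wild-type controls, and each call against wild-type controls, like the interaction, uses the same 3 control libraries. The call between the 2 stressed groups does not use them. With the length slope as a covariate the list mean was -0.49, against -0.47 without it, and the list was still called (camera adjusted p = 4.06e-19), which argues against the length trend between libraries as the whole cause. Without wild-type control replicate 3 the mean was -0.34 (adjusted p = 9.62e-07), so that library carries part of the size and how much of the rest is its own stays open. The 20 members, none of which is in another list, fell between -0.75 and -0.18 with an SD of 0.15 around their mean, including the abundant Mbp (6861 CPM, -0.52) and Mobp (2513 CPM, -0.56); a smaller share of oligodendrocytes or white matter in the punches is a candidate explanation that the uniform shift goes with. A response of oligodendrocytes to prenatal stress stays open beside it, and was not tested separately.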

How the results depend on the processing

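The alternatives for RNA were mostly chosen before the data were examined; the length slope, the fits without the 2 libraries of lowest length slope, RLE and upper quartile scaling of lists, and all 5hmC tests except merging, leaving out X and Y and the overlap settings were chosen only after seeing the data. Of 4633 alternatives of single genes, 4542 kept direction and side of the threshold and 7 reversed. Of 1134 of single lists 916 did and 11 reversed, and of 418 of 5hmC regions 343 did. Apart from Gm6736 the named genes were not called in the main fit. A gene that stayed uncalled with the same sign counts as kept, so the share for genes says little about reliability. Other scaling moved the median of all genes by at most 0.02. The counts below are in the order genotype in controls, genotype in stressed mice, stress in wild type, stress in het, stressed het against unstressed wild type, interaction, stress average and genotype average. The cause of a change was not tested unless fewer samples show it. Genes called by edgeR were 1, 1, 0, 0, 1, 0, 0 and 1 (unadjusted p under 0.05: 235, 91, 397, 179, 204, 212, 374 and 113), by DESeq2 2, 3, 11, 0, 3, 0, 0 and 3. They were by limma-trend 2, 2, 0, 0, 2, 0, 0 and 2, and by limma-voom with sample weights 988, 3, 43, 14, 50, 0, 6 and 10. Fits on the 2 groups only gave 0 for genotype in controls (smallest adjusted p = 0.516) and 0 for stressed het against unstressed wild type (0.0955). With no filter beyond a total above 0 the genotype average had 2 calls, with the length slope as a covariate 4, and with the slope and without the 2 libraries of lowest length slope 8. The last setting gave 203 for genotype in controls, 4 for stress in wild type, 38 for stress in het and 84 for the interaction. Leaving out 1 library gave 0 to 2 for genotype in controls, 0 to 1 for genotype in stressed mice, stress in wild type and stressed het against unstressed wild type, 1 to 2 for the genotype average, and 0 for the others. Lists called by camera with the estimated correlation were 0, 1, 0, 0, 0, 0, 0 and 1, and by fry 0 in each, against 8, 7, 17, 17, 21, 12, 20 and 6 with the preset. The length slope as a covariate gave 10 lists for stress in het and 13 for stressed het against unstressed wild type. Without the 2 libraries of lowest length slope there were 10 for stress in wild type, 11 for stress in het, 6 for stressed het against unstressed wild type and 15 for the genotype average. Both together gave 13 for genotype in controls, 7 for stressed het against unstressed wild type and 14 for the genotype average. Leaving out 1 library gave 8 to 19 lists for genotype in controls, 6 to 16 for genotype in stressed mice, 11 to 18 for stress in wild type, 10 to 18 for stress in het, 7 to 21 for stressed het against unstressed wild type, 5 to 17 for the interaction, 16 to 21 for the stress average and 5 to 19 for the genotype average. Reversed values were Cntnap2 in stressed mice by limma-trend (0.0668) and ribosomal protein genes for stress in het without the 2 libraries of lowest length slope (0.0253). With 1 library left out the mean of that list ran from -0.592 to 0.0254, the last without het control replicate 1. For stress in het the hypothalamus mean reversed without the 2 libraries of lowest length slope (0.134, and 0.123 with the slope as a covariate) and ran from -2.44 to 0.122 with 1 library left out, highest without het control replicate 1. For genotype in controls the ribosomal mean ran from -0.304 to 0.481, reversed without het control replicate 1 or wild-type control replicate 3 (-0.182), and its member Rps6 from -0.0284 to 0.438, reversed by limma-voom with sample weights (-0.0611). In the hypothalamus list, Pmch for stress in het reversed by limma-voom with sample weights (0.220) and without those 2 libraries (0.778, and 0.685 with the slope), and ran from -5.03 to 0.778. The mean of endothelium and mural cells reversed without het control replicate 3 (0.0352). The choroid plexus mean ran from -0.850 to 2.37 for genotype in stressed mice and from -0.910 to 2.45 for the interaction, both lowest without het stressed replicate 3. In the interaction camera also reversed it without het control replicate 3 (mean 1.35). The Cntnap2 difference in log2(TPM + 1) ran from -0.11 to 0.0628 over the libraries left out, with reversals at 0.0628, 0.0274 and 0.00198. Its edgeR value ran from -0.44 to -0.26, and was -0.41 and called with the slope and without the 2 libraries of lowest length slope (adjusted p = 0.00280). The effect correlation ran from -0.0855 to 0.366 for stress and -0.0458 to 0.0551 for genotype.

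The labels do not say whether the replicate numbers pair the mice. In RNA, same-number pairs correlated with a mean of 0.167 and other pairs with -0.0854. These are correlations of deviations from a group mean, so the second mean is tied to the first and is no separate evidence. Of 18 same-number pairs 9 lay above 0.1, and 8 of 12 libraries correlated best with their own number. Replicate 3 had the highest length slope in every group, and the highest same-number correlation (0.674) joined the 2 libraries of lowest slope. The length trend was not separated from pairing. A shared factor behind the numbers is therefore neither shown nor excluded. With the replicate block, RNA calls were 1, 1, 0, 0, 1, 0, 0 and 1 (edgeR, with the unadjusted counts above for the fit without it), and 5hmC calls were 32 for genotype in controls, 17 for stress in het and 1 for stressed het against unstressed wild type. Without the block 5hmC calls were 1, 0, 0, 2 and 3 in the order of the first 5 comparisons (unadjusted p under 0.05: 2863, 1852, 2941, 3203 and 2263), DESeq2 called 0 in each, and limma-voom with sample weights called 5, 0, 12, 15 and 6. Without robust dispersion stress gave 1 in wild type and 20 in het; merging regions within 1 kb gave 15 for stress in het and 0 for stressed het against unstressed wild type, where leaving out X and Y also gave 0 (smallest adjusted p = 0.0616 and 0.0625). Leaving out 1 library gave 0 to 7, 0 to 4, 0 to 7, 0 to 60 and 0 to 18. Overlap was 20.3% (genotype) and 26.1% (stress) in the part of each table with p below its median, and 57.6% for stress at 50% overlap; relative to the union it was 0.834 and 0.842. A stricter set of 5hmC regions by the authors' p, and the tests of 5hmC regions against RNA with genes under an unadjusted p of 0.05, with gene length bins and with the stricter set, were not run.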

Other observations

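The tests of explanations in this part, and the permutation of list means, were chosen only after the results were seen. Cortical excitatory neuron genes, which mark tissue next to the striatum, were higher in stressed than unstressed het mice (median log2 fold change 0.47, camera adjusted p = 0.00644; adjusted p = 0.625 with an estimated correlation), and hypothalamus genes lower (median -1.30, adjusted p = 0.00213; adjusted p = 0.625 with an estimated correlation). The cortical list was not called without het stressed replicate 2 (adjusted p = 0.0819) or het control replicate 3 (0.314), and the hypothalamus mean reversed without het control replicate 1 (adjusted p = 0.580). Over all genes, the edgeR fit with the length slope as a covariate and without the 2 libraries of lowest slope called the cortical markers Neurod2 (1.64), Tbr1 (1.78), Nrn1 (1.95), Neurod6 (2.31) and Slc17a7 (2.33) higher, and Rspo1 of that list lower (-0.95). The stress axis genes Htr1a (1.31) and Bdnf (2.15) were called higher in the same fit. Stress axis genes with Htr2a, and synaptic scaffold genes, were higher in the same comparison. More cortex in these punches is a candidate explanation for them, and whether it accounts for them was not tested. Permuting list means over 6 stressed and 6 control mice, the smallest exact p among 34 lists were 0.0238 for interferon genes (difference -0.42) and 0.0455 for choroid plexus genes (-1.88), both with an adjusted p of 0.626. For genotype the smallest was 0.0801 for immature neuron genes (-0.21, adjusted p = 0.984).

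Xist, the RNA that coats the inactive X chromosome, was at 1.32 TPM (50 counts) in wild-type stressed replicate 2, against 23.1 to 109 TPM in the other 11 libraries. Under-recovery of long transcripts is argued against: the 442 genes at least as long had a median deviation of -0.10 on the log2 scale in this library, where Xist had -6.80. A single X chromosome in this animal, by loss of an X or because it was male, goes with both kinds of data. The mean of Eif2s3x, Kdm6a, Kdm5c and Ddx3x, genes that escape X inactivation, lay 0.45 below its length slope's prediction (-0.45, lowest other library -0.07). The animal's median 5hmC deviation over 16 X regions was -0.40 (lowest other -0.02), and over 19 regions in the table of wild-type mice -0.15 (lowest other 0.09). Which of these holds was not analysed here.

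Gm6736 and Gm10800 RNA followed the genotype in all libraries, and a 5hmC region on chromosome 6, which also carries Cntnap2 in GRCm38.p6, was lower in both het groups than in wild-type controls. DNA linked to the targeted allele is a candidate explanation, in which changes would gather on chromosome 6. Of 749 genes on chromosome 6, 1.20% had an unadjusted p under 0.05 for the genotype average, against 0.561% elsewhere (Fisher exact p = 0.0435, odds ratio 2.16, 95% interval 0.948 to 4.33), but a chromosome was known for only 78.8% of the genes under that p, under the 80% asked for, so this test leaves RNA open. For 5hmC, chromosome 6 held more such regions in controls (8.88% against 7.43%, Fisher exact p = 0.0134, 0.267 adjusted over chromosomes, odds ratio 1.21, 95% interval 1.04 to 1.41), an excess that is nominally above 1 and yet under the bound of 1.5 set against linkage, so it leaves the question open. It held no more in stressed mice (7.02% against 7.44%, Fisher exact p = 0.609, odds ratio at most 1.16). This argues against an excess over the whole chromosome there, but cannot exclude a short linked segment. The called chromosome 6 region could not count, as it is not among the regions of that comparison. A chromosome 6 region at 47727622 was lower in stressed het mice but did not pass with all libraries. It passed without het stressed replicate 1 (edgeR adjusted p = 0.01001) or wild-type stressed replicate 1 (0.00522). Of the genes separating all het from all wild-type libraries, Atp6v0c-ps2 is placed on chromosome 6 and Gm6736 on chromosome 12 in that assembly, and reads from a near-identical copy were not tested.

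Where 3 libraries face 3, the 10 splits are too few for a share under 0.05. Genes called by edgeR were 1 in the real split and 5217 in the highest other for genotype in controls (2 of 10 splits as large), 1 and 0 for genotype in stressed mice (1 of 10), 0 and 0 for stress in wild type (10 of 10), 0 and 8 for stress in het (10 of 10), and 1 and 0 for stressed het against unstressed wild type (1 of 10). The same order for lists called gave 8 and 17 (10 of 10), 7 and 19 (9 of 10), 17 and 20 (2 of 10), 17 and 19 (3 of 10), and 21 and 15 (1 of 10). For 5hmC regions it gave 1 and 22 (6 of 10), 0 and 5 (10 of 10), 0 and 5 (10 of 10), 2 and 14 (2 of 10), and 3 and 78 (3 of 10). Among 100 splits, the genotype average gave 1 gene and 6511 in the highest other, with 3 of 100 as large, a share under 0.05, and 6 lists against 20, with 96 of 100 as large. The stress average gave 0 genes and 0 in the highest other (100 of 100; 374 genes at an unadjusted p under 0.05 by edgeR, 0 by DESeq2), and 20 lists against 23, with 4 of 100 as large, a share under 0.05. Splits that call 5217 or 6511 genes point to a structure of the samples. Its cause was not tested. Where the real count is 0, as many calls in all splits tells nothing.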
